A study of Pseudomonas aeruginosa with 4 samples.

How the data were processed

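The data are 4 RNA libraries from anaerobic cultures of P. aeruginosa PAO1, 1 each for the control and for 1, 10 and 50 mg/L CuO nanoparticles. Per the labels' protocols, total RNA was extracted 2 h after the nanoparticles were added and strand-specific cDNA libraries were made. The protocol also names a dose of 0.1 mg/L, which is not analysed here. The labels do not say whether further cultures stood behind each library.

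The authors deposited 3 tables, each pairing 1 dose with the control, with 5554 genes in each. Per the file headers, each table holds the count per gene, the RPKM per gene, the log2 ratio of treated over control, a p-value and an FDR. The control columns were checked to be the same in the 3 tables. Each deposited RPKM was checked to equal the count per kb of gene length scaled by the counts summed over the listed genes, so this total sets the scale. The log2 ratio in the authors' deposited tables is that of the RPKM values, with an RPKM of 0 replaced by about 0.001. Per the submitters' processing notes, Cufflinks 2.2.1 and Cuffdiff were used, without a statement of what each made. The aligner, the counting, the genome build and the test behind the deposited p-value are not given in the sources used here. How reads shared between near-identical genes were assigned is likewise not given, so genes of the duplicated phenazine operons are uncertain and none is named. No coordinates are given because no build is named.

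Of the 5554 gene identifiers, 5511 matched locus tags of a RefSeq gene table (assembly ASM676v1), used only to look for rRNA and tRNA genes, and 43 did not. None of the matched genes was an rRNA or tRNA gene, so leaving these out removed nothing. Gene names and products are those of the deposited tables.

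The main measure was log2((treated RPKM + 1)/(control RPKM + 1)), over genes with a mean RPKM of at least 10 in the 2 libraries. The plan had named FPKM as the unit; the tables hold RPKM, and the same rule was used on it. With 1 library per group no p-value was computed. Genes past a ratio of 1 or -1 (2-fold) were counted, as deposited and centred on the median ratio. Named genes were fixed by a rule set before the data were examined: per dose the 10 largest increases and the 10 largest decreases among tested genes, and from each list up to 4 members with the largest ratio in size at 50 mg/L. Genes outside it are marked as chosen after their values were seen. The 34 gene lists were fixed before the data were examined and matched by locus tag, or by symbol where the tables gave the listed symbol to another tag. A list's median was set against 10000 random lists of the same size, drawn with replacement from genes in the same deciles of mean RPKM, and lists with under 3 tested members got values only. Fold intervals are 95% Clopper-Pearson intervals of the treated share of the 2 counts. They and the intervals of shares cover counting error only, since reads without molecular identifiers are not independent molecules.

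Overlaps between doses were set beside the product of the list sizes over the genes tested, and beside 100 simulated draws of unchanged libraries sharing 1 control. The simulated noise per decile of expression came from the spread of the 1 mg/L ratios, which includes any effect of that dose.

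The calculation was tested on simulated counts with 50 genes changed by each of 4 known folds. For each of the 3 comparisons, all 50 genes passed 2-fold relative to the median gene at each of 4-fold higher, 4-fold lower, 8-fold higher and 8-fold lower. Of the unchanged genes, 1 of 4541 passed 2-fold at 1 mg/L, 1 of 4521 at 10 mg/L and 2 of 4540 at 50 mg/L. Of 100 unshifted lists, 5, 1 and 2 lay outside the central 95%. These simulations hold counting error and no variation between cultures.

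Alternatives planned before the data were examined were pseudocounts of 0.1 and 10, no filter, a mean RPKM of at least 50, centred ratios, libraries rescaled to the same RPKM total, the authors' FDR under 0.05 added to the size rule, all genes kept, the control averaged over the tables, the authors' status, and unmatched random lists. Added afterwards were library totals without the Pf genes, edgeR TMM factors, DESeq2 size factors and the 1 mg/L library as the baseline. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.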

Results

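Pseudomonas aeruginosa PAO1, a reference strain of a bacterium that can respire nitrate when oxygen is absent, was cultured anaerobically on glycerol with nitrate and exposed to copper oxide (CuO) nanoparticles. RNA was taken at 13 h of incubation, 2 h after nanoparticles had been added to 1, 10 or 50 mg/L, and from a culture without them. For 1 mg/L the sample's own label gives the 13 h without naming the exposure, and the 2 h follows from the protocol common to all samples. Each dose and the control had 1 library, so there was no spread between replicates and no test of a dose was made. Every difference below is one between these 4 libraries, and all 3 doses were set against the same control library. Counts over 5554 genes summed to 8655306 in the control and to 6972777, 6801826 and 7260626 at 1, 10 and 50 mg/L. The comparisons ask how transcript levels at each dose differed from the control, and how the doses differed from one another.

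The median gene lay below the control at every dose, at a log2 ratio of -0.41 at 1 mg/L, -0.52 at 10 mg/L and -0.51 at 50 mg/L. Log2 ratios of genes and gene lists are therefore given relative to the median gene of the same comparison, unless they are called ratios as deposited. Log2 ratios called as deposited keep the deposited scale without centring. All log2 ratios were formed from RPKM plus 1, so they differ from the authors' own ratios, most at low RPKM. Levels given as times that of the control were formed without the added 1. Counting error alone gave a 95% interval with a median half-width of 0.22 on the log2 scale at 1 mg/L, 0.23 at 10 mg/L and 0.22 at 50 mg/L. These intervals cover counting error only and not the variation between cultures. A gene list is said to have risen or fallen where its median lay outside the central 95% of 10000 random lists matched on mean expression. This describes these libraries and is not a test. Random lists draw genes singly, while many lists hold genes of 1 operon that may move together, so the range can be too narrow. Lists with 3 or more tested genes numbered 33, 34 and 33 at 1, 10 and 50 mg/L. No correction for their number was made, so some may lie outside by chance.

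The highest ratios at every dose belonged to the Pf prophage, a filamentous phage integrated in the PAO1 chromosome. Its 11 core genes, PA0717 to PA0728 as far as the tables list them, made up all of the 10 largest increases at 1 mg/L, 8 of the 10 at 10 mg/L and 9 of the 10 at 50 mg/L. The gene for coat protein B, coaB (PA0723), had 711 counts in the control and 1007502, 985327 and 788466 counts at 1, 10 and 50 mg/L. Its log2 ratios were 11.19, 11.30 and 10.87. PA0720, the phage's helix-destabilizing protein, stood at 11.11, 10.97 and 11.46, and the probable integrase gene PA0728 at 9.76, 9.50 and 9.37. The core genes took 0.0205% of all counts in the control (exact Clopper-Pearson 95% interval 0.0195% to 0.0214%). At 1 mg/L they took 28.8% (28.8% to 28.9%), at 10 mg/L 26.6% (26.5% to 26.6%) and at 50 mg/L 24.4% (24.3% to 24.4%). Over the 14 tested members of the Pf list, the median as deposited was 9.28, 9.02 and 8.97, or 9.70, 9.54 and 9.48 relative to the median gene. At each dose 12 members were at least 2-fold above the median gene. The other members, PA0715 and PA0716, named after their values were seen, stood at 0.89, 0.93 and 1.00 and at 0.72, 0.69 and 0.55.

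**Figure D1:**
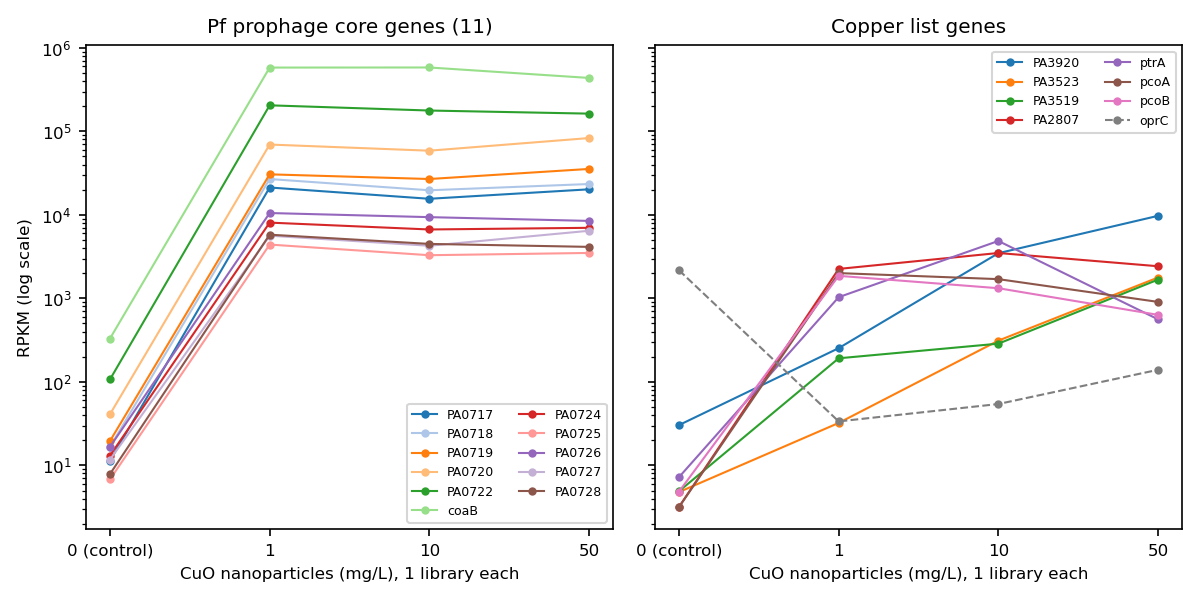
RPKM on a log axis in the 4 libraries, by CuO dose in mg/L, for the 11 Pf core genes (left) and 8 genes of the copper list (right). Each point is 1 library and lines join the points of a gene. The coaB counts went from 711 in the control to 1007502 at 1 mg/L, and oprC, drawn dashed, fell from 40809 to 509.

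Copper homeostasis genes rose at every dose, and their median was higher with each dose. The median of the 20 tested members as deposited was 3.04 at 1 mg/L, 4.53 at 10 mg/L and 6.65 at 50 mg/L, or 3.46, 5.05 and 7.16 relative to the median gene. At each dose 18 of the 20 were at least 2-fold above the median gene. PA3920, a probable metal-transporting P-type ATPase, had log2 ratios of 3.43, 7.31 and 8.79, with 625 counts in the control and 168127 at 50 mg/L. The probable efflux membrane fusion protein gene PA3523 had ratios of 2.93, 6.28 and 8.77, and PA3519, a hypothetical protein, 5.44, 6.13 and 8.66. Other members were already near their highest level at the lowest dose. PA2807, a hypothetical protein, stood at 9.49, 10.23 and 9.69, and as deposited its 50 mg/L level was 763 times that of the control, with a counting interval of 476 to 1310 because the control held only 17 counts. The copper resistance gene pcoA (PA2065), chosen after its values were seen, had ratios of 9.33, 9.19 and 8.28, and pcoB (PA2064), chosen likewise, 8.73, 8.34 and 7.27. The highest ratio of ptrA (PA2808), named as a repressor of type III secretion, was at 10 mg/L, with 7.39, 9.73 and 6.60. The gene for the copper transport porin OprC (PA3790) fell, with ratios of -5.56, -4.78 and -3.44, and its counts were 40809 in the control and 509, 802 and 2199 with rising dose.

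The lists of zinc and cadmium efflux and of lipid A modification also rose at every dose. The czc list, named for a cation efflux pump, had a median of 3.09 over 7 members at 1 mg/L, 4.49 over 8 at 10 mg/L and 2.96 over 5 at 50 mg/L. Of these members 4, 5 and 3 were at least 2-fold above the median gene. At 50 mg/L the 3 were czcR, czcS and PA3690, and none of the pump genes czcA, czcB and czcC was among them. The members tested differed between doses because some did not meet the minimum mean RPKM at each dose. The response regulator gene czcR (PA2523) stood at 4.51, 5.85 and 4.81. PA3690, another probable metal-transporting P-type ATPase, had values of 0.41 and 0.32 at the lower doses and 3.47 at 50 mg/L. In the polymyxin resistance and PhoPQ list, whose arn genes add aminoarabinose to lipid A, the medians were 3.26, 1.25 and 2.36, and 14, 9 and 12 of the 15 members were at least 2-fold above the median gene. The outer membrane protein gene oprH (PA1178) stood at 3.87, 3.43 and 4.15, and arnB (PA3552) at 3.61, 2.42 and 3.31.

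Multidrug efflux genes rose at 10 mg/L and 50 mg/L, with medians of 1.13 and 0.55 over 20 members. Relative to the median gene 11 members were at least 2-fold higher and 2 lower at 10 mg/L, and 9 higher and 0 lower at 50 mg/L, and as deposited 7 were higher and 4 lower, and 6 higher and 2 lower. At 1 mg/L their median was 0.10, at percentile 70.2 of the random lists, and without a filter on low values, over 25 members, it lay above them at percentile 97.8. The pump gene muxA (PA2528) had ratios of 1.46, 6.06 and 4.84, and mexA (PA0425) 0.01, 2.70 and 2.44. PA1435, of another pump of this family, had 4.63, 5.31 and 3.20. The list of heme and ferrous iron uptake had medians of 0.61, 1.19 and 0.77, above the random range at each dose, and phuR (PA4710), a heme receptor, stood at 1.39, 1.76 and 1.43. Of its 10 tested members 2, 6 and 3 were at least 2-fold above the median gene and 0, 0 and 1 below it, and as deposited 1, 4 and 1 were higher and 0, 2 and 2 lower. PA4707, a probable permease of an ABC transporter, stood at -0.41, -0.60 and -1.25. Zinc uptake genes rose at 10 mg/L, with a median of 1.16 over 14 members, and had medians of 0.33 and 0.57 inside the random range at 1 and 50 mg/L. Heat shock and protease genes rose at 1 and 10 mg/L, with medians of 0.49 and 0.82 against 0.37 at 50 mg/L. At 1 and 10 mg/L 2 and 7 of the 17 members were at least 2-fold above the median gene and 0 below it. As deposited, 1 and 2 were higher and 0 and 1 lower. Among those higher, hslU (PA5054), of an ATP-dependent protease, was as deposited at 2.81, 3.22 and 1.85 times its control level at 1, 10 and 50 mg/L. As deposited, the medians of the zinc list at 1 mg/L, the heat shock list at 50 mg/L and the multidrug list at 1 mg/L were below 0. With libraries rescaled to the same RPKM total, the medians of the heme and heat shock lists where they rose, of multidrug efflux at 10 and 50 mg/L and of zinc uptake at 10 mg/L were below 0, still above those of most random lists.

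Genes of nitrate respiration and denitrification fell at 50 mg/L. The nar list holds genes of the membrane-bound nitrate reductase and its transporters and the regulatory genes narX and narL. Its medians as deposited were -0.35, -1.01 and -2.67. Relative to the median gene these were 0.06, -0.49 and -2.16, at percentiles 65.3, 14.1 and 0 of the random lists, and 6 of the 8 members were at least 2-fold below it at 50 mg/L. The transporter gene narK2 (PA3876) had ratios of -0.09, -0.99 and -3.33, and narG (PA3875), the catalytic subunit, -0.13, -0.74 and -2.45. The nap genes of the periplasmic nitrate reductase fell at 50 mg/L, with a median of -1.41 over 6 members, against -0.41 and -0.28 at 1 and 10 mg/L. The nir list of nitrite reduction had medians as deposited of -0.52, -1.15 and -1.37, or -0.10, -0.63 and -0.86 relative to the median gene. For nos, nitrous oxide reduction, they were -0.68, -1.24 and -1.42, or -0.27, -0.72 and -0.91. Both lists fell at 50 mg/L, at percentiles of 1.10 and 1.08, with 3 of 12 nir and 2 of 6 nos members at least 2-fold below the median gene. As deposited, 12 of 12 nir and 6 of 6 nos members were at least 2-fold lower at 50 mg/L, and 11 of 12 and 5 of 6 at 10 mg/L. At 10 mg/L their percentiles were 7.21 and 7.83, inside the random range. The gene nirC (PA0517) stood at -0.50, -1.08 and -1.53, and nosZ (PA3392), the nitrous oxide reductase, at -0.56, -0.86 and -0.93. The median of nor, nitric oxide reduction, was -0.75 at 50 mg/L, at percentile 8.85. A list of other anaerobic energy genes had medians of 0.20, 0.20 and -1.02 (below 0 at every dose as deposited) and fell at 50 mg/L, where 10 of its 18 members were at least 2-fold below the median gene. In it ccoN2 (PA1557), a terminal oxidase subunit, stood at 0.23, 0.03 and -1.85.

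**Figure D2:**
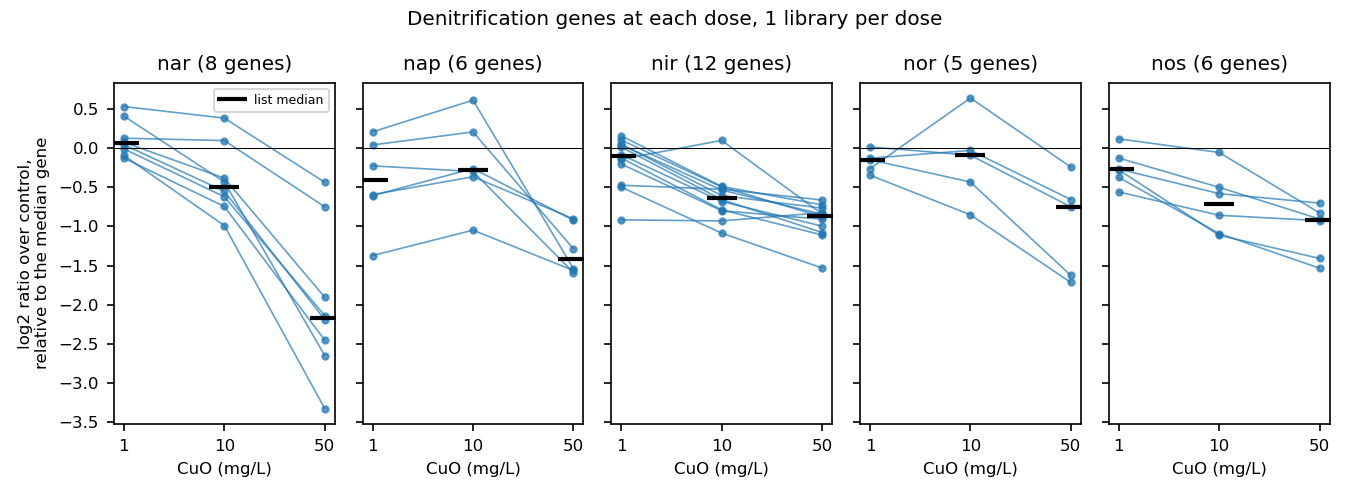
Log2 ratio over the control, relative to the median gene, of each tested gene of the 5 denitrification lists by CuO dose in mg/L. Each point is 1 gene in 1 library, thin lines join the points of a gene and black bars are list medians. The nar median went from 0.06 at 1 mg/L to -2.16 at 50 mg/L.

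Several lists fell at every dose. Ribonucleotide reductase genes, which supply deoxynucleotides, had medians of -1.65, -1.60 and -2.22, with 5 of 6 members at least 2-fold below the median gene at each dose. The gene nrdG (PA1919), the activator of the anaerobic enzyme, stood at -2.17, -2.91 and -3.79, and nrdJb (PA5496) at -1.70, -1.96 and -2.98. The R and F pyocins, phage tail-like bacteriocins, had medians as deposited of -1.25, -1.60 and -1.50 over 39 genes, or -0.83, -1.08 and -0.99 relative to the median gene. Of these genes 6, 23 and 19 were at least 2-fold below the median gene, and 1 was at least 2-fold above it at 10 and at 50 mg/L. As deposited, 32, 36 and 36 were at least 2-fold lower than in the control and 0 higher. PA0614 of this cluster stood at -0.58, -0.97 and -2.42. The exopolysaccharide list, which pools alginate, Psl and Pel genes, had medians of -0.74, -1.13 and -1.17 over 20, 19 and 18 of its 30 members. Of these 5, 11 and 10 were at least 2-fold below the median gene. The gene pslH (PA2238), of the Psl polysaccharide, had ratios of -0.97, -1.74 and -2.14.

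Other lists fell at some doses. H1 type VI secretion genes, which encode a contractile protein injection machine, had medians of -1.12 and -1.22 at 1 and 10 mg/L and of -0.30 at 50 mg/L, at percentile 12.8. Of 18 members, 12, 13 and 0 were at least 2-fold below the median gene, and 16, 17 and 5 below the control as deposited. The ATP synthase genes had medians of -0.74 and -1.50 at 1 and 10 mg/L and -0.09 at 50 mg/L, at percentile 30.5. Glycerol use genes fell at 1 and 10 mg/L, with medians of -1.09 and -1.32, and had a median of -0.99 at 50 mg/L, at percentile 3.09, which was below the random range with a pseudocount of 10 (1.78), a minimum mean RPKM of 50 (1.97), unmatched random lists (1.57), totals without Pf genes (2.48) or TMM factors (2.42). The glycerol kinase gene glpK (PA3582) stood at -1.82, -2.65 and -1.54. Ribosomal protein genes fell at 10 mg/L, with a median of -0.67, and had medians of -0.29 and -0.23 at 1 and 50 mg/L, the former below the range of unmatched random lists. Secreted virulence factors fell at 1 and 50 mg/L, with medians of -0.60 and -1.11, and had a median of -0.48 at 10 mg/L, at percentile 7.18. Of 13 tested members 6, 4 and 7 were at least 2-fold below the median gene and 1, 2 and 0 above it. The gene hcnC (PA2195), of hydrogen cyanide synthesis and the lowest of them at 10 and 50 mg/L, stood at -2.28, -3.25 and -3.94. S pyocins fell at 10 mg/L, with a median of -1.07 at percentile 2.06, and had medians of -0.58 and -0.33 at 1 and 50 mg/L, at percentiles 4.84 and 18.6. Type IV pili fell at 50 mg/L, with a median of -0.49, and had medians of -0.17 and -0.29 at 1 and 10 mg/L, at percentiles 10.7 and 13.7. With a minimum mean RPKM of 50, these medians of S pyocins at 10 mg/L and of pili at 50 mg/L and that of the zinc list at 10 mg/L lay inside the random range, while that of pili at 1 mg/L lay below it, at percentile 1.69. The S pyocin median at 10 mg/L also lay inside the range, at percentile 2.63, with libraries rescaled to the same RPKM total. Differences between doses in these lists were not tested.

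Flagellar genes rose at 1 mg/L relative to the median gene, with a median of 0.34, which as deposited was -0.08. Of the 39 members 2 were at least 2-fold above the median gene, and 1 was at least 2-fold above the control as deposited. The SOS response list rose at 50 mg/L, with a median of 0.69 at percentile 98.2, which was below 0 with libraries rescaled to the same RPKM total, and it lay inside the random range with edgeR or DESeq2 scaling. Within it PA3413 stood at 0.34, 1.28 and 1.58, and PA0671 at -1.15, -1.57 and -1.44. Medians inside the random range at every dose, where 3 or more members were tested, were those of nor, oxidative stress, SoxR targets, iron-sulfur cluster assembly, envelope stress, pyoverdine, pyochelin, quorum sensing and type III secretion. Few members were tested of type III secretion (10, 10 and 9 of 39) and of pyoverdine (2, 3 and 1 of 19). Some alternatives put their medians outside the range, namely type III secretion at 50 mg/L (percentile 1.24) and pyoverdine at 10 mg/L (98.3) without a filter, pyoverdine at 10 mg/L with TMM (97.8) or DESeq2 (97.8) factors, and envelope stress at 10 mg/L against unmatched lists. The oxidative stress list held genes that moved apart. The peroxidase gene ahpC (PA0139) stood at 1.27, 1.58 and 3.17 and the organic hydroperoxide resistance gene ohr (PA2850) at -0.34, -0.03 and 2.90, while the catalase gene katA (PA4236) stood at -1.18, -1.13 and -1.96. In the iron-sulfur list iscR (PA3815) stood at 1.01, 2.18 and 2.94 and PA3808 at -0.17, -0.42 and -1.02, and at 50 mg/L 3 of its 8 members were at least 2-fold above the median gene and 1 below it, or 2 and 2 as deposited.

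**Figure D3:**
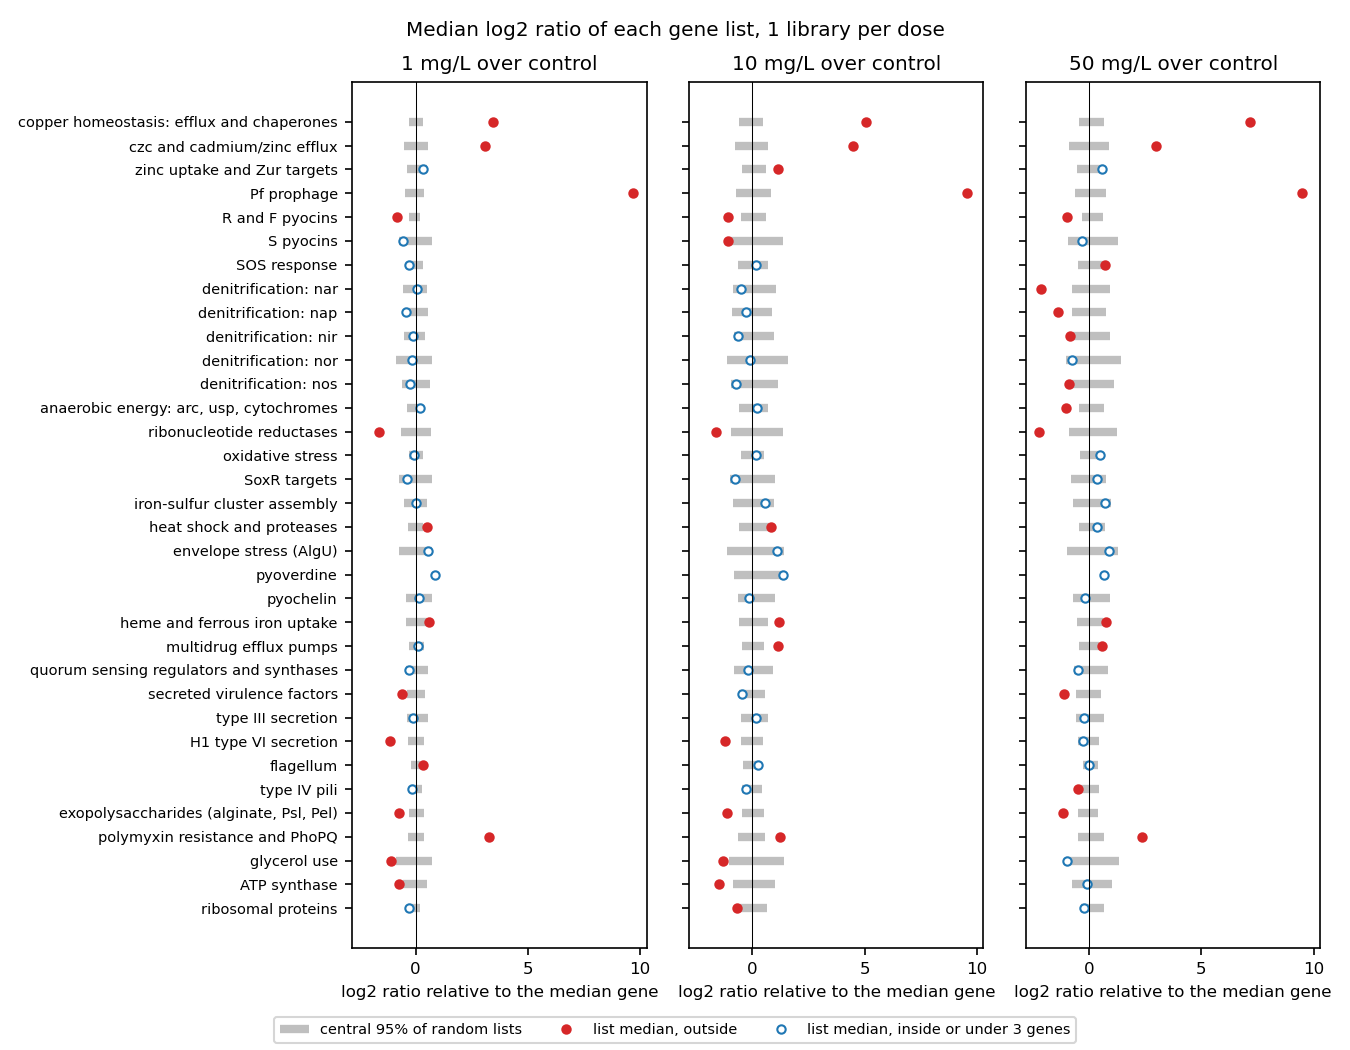
Median log2 ratio of each of the 34 gene lists at 1, 10 and 50 mg/L over the control, relative to the median gene. Grey bars are the central 95% of 10000 random lists, filled points lie outside them and open points inside or on lists with under 3 tested genes. The Pf list stood at 9.70, 9.54 and 9.48 and the copper list at 3.46, 5.05 and 7.16.

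The largest decreases were led by genes outside these lists. PA1210, a conserved hypothetical protein, stood at -6.57, -5.53 and -5.64, with 9055 counts in the control and 53, 103 and 102 at the doses. The azoreductase gene azoR3 (PA3223) stood at -6.11, -6.17 and -5.34 and PA3240 at -6.05, -5.05 and -4.11. PA2839 had ratios of -5.16, -4.57 and -4.92, PA2122 of -4.32, -5.17 and -4.75, and PA1168 of -4.52, -5.17 and -2.64. Neighbouring genes from PA3327 to PA3335 held 5 of the 10 largest decreases at 1 mg/L, and 6 of the 10 at 10 and at 50 mg/L. Among them PA3332 stood at -5.06, -6.44 and -5.13, and fabH2 (PA3333), a ketoacyl synthase gene, at -4.76, -5.67 and -4.76.

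By the size rule alone, 217 genes were at least 2-fold higher and 787 at least 2-fold lower at 1 mg/L as deposited, of 4767 tested. At 10 mg/L 448 were higher and 1462 lower of 4804, and at 50 mg/L 347 were higher and 1325 lower of 4748. Higher genes were 21.6%, 23.5% and 20.8% of these. Centred on the median gene, 431 were higher and 367 lower at 1 mg/L, 781 and 676 at 10 mg/L, and 664 and 572 at 50 mg/L, so that higher genes were 54.0%, 53.6% and 53.7%. In the authors' deposited table, whose test is not stated, 3970, 4325 and 4263 genes had an FDR under 0.05, values that compare 2 libraries and not conditions.

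Between 50 and 10 mg/L, 300 genes were at least 2-fold higher and 359 at least 2-fold lower at the larger dose, of 4569 tested, with a median ratio of 0.04. PA3920, PA3523 and PA3519 of the copper list and PA3690 were among the genes higher at 50 mg/L, and ptrA and the nar genes narG and narK2 among those lower. From 1 to 10 mg/L 247 were higher and 211 lower of 4623, and from 1 to 50 mg/L 275 higher and 303 lower of 4579. Centred on the median gene these were 279 and 379 for 50 over 10 mg/L, 317 and 137 for 10 over 1 mg/L, and 330 and 239 for 50 over 1 mg/L. Each treated library was closer to the other treated libraries than to the control, though for 1 with 50 mg/L by a small margin in spread. For 1 mg/L the Pearson correlation of log2(RPKM + 1) across genes was 0.84 with the control. It was 0.94 with 10 mg/L and 0.92 with 50 mg/L. The robust SD of centred log2 ratios was 0.51, 0.59 and 0.61 between treated libraries (10 over 1, 50 over 1 and 50 over 10 mg/L), and 0.61, 0.95 and 0.86 for 1, 10 and 50 mg/L over the control.

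Centred on the median gene, 363 genes were at least 2-fold higher at both 1 and 10 mg/L and 308 lower at both. For 1 and 50 mg/L these were 290 and 241, and for 10 and 50 mg/L 439 and 346. Independent lists of the same sizes would share 65.2 and 52.4, 54.2 and 44.6, and 97.1 and 82.4. Simulated unchanged libraries against 1 shared control gave 65.2 and 63.5, 62.8 and 63.4, and 64.3 and 63.9. The noise of the 1 mg/L ratios was used for all 3 pairs. Their robust SD was 0.61, against 0.95 at 10 mg/L and 0.86 at 50 mg/L. The simulated overlaps may therefore be too low, and for 10 with 50 mg/L they lay below those of independent lists. The covariance of the log2 ratios, with the Pf genes included, was 1.25, 1.10 and 1.44 for the 3 pairs. It was 0.19 in each simulation, a value set by the same 1 mg/L noise. The simulated control had the same noise as a treated library, so a control that stands apart was not simulated. The real control could not be split, so part or all of each excess may come from it. As deposited, 193 genes were higher and 687 lower at both 1 and 10 mg/L, 155 and 585 at 1 and 50 mg/L, and 227 and 950 at 10 and 50 mg/L, where independent lists would share 18.6 and 243, 14.3 and 222, and 28.1 and 411.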

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

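All tests in this part were chosen only after the results were seen, and the differences between doses given here were not tested, since each dose had 1 library. A few genes were at least 2-fold above the control at one dose and at least 2-fold below it at another. As deposited there was 1 such gene between 1 and 10 mg/L (PA2480), 6 between 1 and 50 mg/L (PA0777, PA1429, fahA, PA5396, PA5397 and dgcA) and 7 between 10 and 50 mg/L (PA1260, PA1414, fahA, PA2753, PA3309, PA5396 and PA5397). Relative to the median gene there were 0, 4 and 2. Of the genes counted as deposited, 0, 2 and 2 were also counted relative to the median gene. The fahA gene, of homogentisate breakdown and like the others chosen after its values were seen, had log2 ratios as deposited of -1.75, -2.28 and 1.81 at 1, 10 and 50 mg/L.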

How the results depend on the processing

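Tests with library totals without Pf genes, edgeR TMM factors, DESeq2 size factors or the 1 mg/L baseline were chosen only after the results were seen. Each set of 3 values below follows the order 1, 10 and 50 mg/L, or for overlaps 1 with 10, 1 with 50 and 10 with 50 mg/L. No paired analysis was possible because each group had 1 library. The tallies in this paragraph count cases, each being 1 result under 1 alternative. Each alternative is compared with the ratios as deposited. The signs are thus those of medians not centred on the median gene, unlike most medians given above. List medians planned as main results kept their side of the random range in 179 cases and moved outside it in 1, and their sign changed in 4 cases, all inside the range. The other list medians kept their side in 784 cases, moved outside in 13 and inside in 6. Their sign changed in 75 cases, 61 of them inside the range under both settings, and the other 14 are given below. Counts stayed within 1.5 times in 35 cases and not in 38, and overlaps in 20 and not in 34. Values of named genes moved past their counting interval in 2237 cases and not in 1948. The cause was not tested for any of these, except that a scaling shifts all ratios of a comparison alike by construction. Centring and the rescalings thus move a list and its random lists together. In those cases the side of the random range was nearly fixed in advance, so they are little evidence that a list result is stable.

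Centred on the median gene, 431, 781 and 664 genes were higher and 367, 676 and 572 lower, with overlaps of 363, 290 and 439 higher and 308, 241 and 346 lower. Without the Pf genes in the totals these were 508, 719 and 599 higher and 339, 776 and 717 lower, with overlaps of 398, 305 and 394 and of 298, 247 and 431. TMM factors gave 385, 757 and 636 higher and 382, 691 and 593 lower, with overlaps of 328, 269 and 421 and of 325, 256 and 364. DESeq2 factors gave 370, 729 and 624 higher and 402, 728 and 613 lower, with overlaps of 315, 262 and 406 and of 340, 267 and 379. The flagellum median at 1 mg/L was 0.34 when centred, 0.42 without the Pf genes, 0.31 with TMM and 0.28 with DESeq2.

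Rescaled to the same RPKM total over the genes used, 113, 209 and 195 genes were higher and 2720, 2953 and 2579 lower, with overlaps of 93, 89 and 106 and of 2360, 2063 and 2255. The median gene then stood at -1.10, -1.23 and -1.08. This rescaling put below 0 the medians of heat shock at 1 and 10 mg/L (-0.61, -0.43), heme uptake at the 3 doses (-0.46, -0.0183, -0.29), zinc uptake at 10 mg/L (-0.0676), multidrug efflux at 10 and 50 mg/L (-0.11, -0.53) and SOS at 50 mg/L (-0.40). All of these stayed above the median gene of the same dose. With a mean RPKM of at least 50, 280 genes were higher at 10 mg/L and 427, 881 and 734 lower, the higher overlap of 1 with 10 mg/L was 125, the lower overlaps were 371, 312 and 541, and 379 genes differed between 50 and 10 mg/L. Fewer genes were tested there. Without a filter the multidrug efflux median at 1 mg/L was 0.0042. Against unmatched random lists the nir median at 10 mg/L, -1.15, lay outside the central range. With the 1 mg/L library as the baseline, 247 genes were higher and 211 lower at 10 mg/L, and 303 lower at 50 mg/L.

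Keeping all genes changed nothing, since no rRNA or tRNA gene was found among the matched identifiers and none was left out. Averaging the control over the tables changed nothing, since it was the same in each table. A selection on the authors' status was not run because the tables hold no such column. Depth limits genes with few control counts most, as in PA2807, and the lack of replicates leaves the spread between cultures unknown.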

Other observations

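All tests in this part were chosen only after the results were seen, and so were the gene groups named here. Ratios of groups are medians of log2 ratios as deposited. At 50 mg/L the arsenic resistance genes arsR, arsB and arsC stood at 3.77, against -0.19 at 1 mg/L and 0.24 at 10 mg/L, and all 3 were at least 2-fold higher at 50 than at 10 mg/L. These group medians take every member, without the minimum mean RPKM. It was not met by arsR at 1 mg/L (23 counts in the control and 16 at this dose) or by arsB at 1 and 10 mg/L. The sulfate-binding protein gene sbp stood at 2.08, 1.43 and 4.90 at 1, 10 and 50 mg/L, and PA3938, a probable taurine-binding protein, at 1.20, 0.47 and 3.58, while the taurine dioxygenase gene tauD stood at 0.23, -0.02 and 0.23. Of the genes for homogentisate breakdown, maiA stood at -0.09, -0.90 and 3.45, fahA at -1.75, -2.28 and 1.81, and hmgA at -2.65, -2.96 and 0.19. The magnesium transport ATPase gene mgtA stood at -0.71, 3.23 and 0.31.

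Other groups were lower at every dose. Of 12 genes of the H2 type VI secretion system, 11, 12 and 12 were at least 2-fold lower at 1, 10 and 50 mg/L, with medians of -2.43, -3.22 and -2.57. The 9 genes from PA3327 to PA3335 had medians of -5.12, -5.99 and -5.26. The 4 genes of acetoin and butanediol metabolism stood at -2.73, -4.01 and -3.43, and the 4 genes ambB to ambE at -2.95, -3.15 and -3.55.

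The Pf core genes were about equally high in the 3 treated libraries. Phage DNA carried into the libraries would cover the genes evenly, and the highest core gene had at least 125 times the RPKM of the lowest in each treated library (125 to 177), which argues against it as the whole source. A response graded with dose stays open, since the median log2 ratio of 50 over 1 mg/L was -0.21 (-0.49 to 0.26 over the genes) but each dose had 1 library. That the control stands apart stays open too, as its 0.0205% of counts on these genes comes from 1 library. Induction of the phage by CuO at or below 1 mg/L may also account for the pattern and is an untested hypothesis.

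The median gene was lower in every treated library. Counts taken by the Pf genes may account for this, since without them in the totals the median ratio was between -0.10 and 0.08 at the 3 doses. That value fits a share of counts moved to the phage and says nothing of RNA per cell. No biological explanation of the shift was tested.

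At all 3 doses 99 genes were at least 4-fold lower as deposited. Counts taken by the Pf genes are argued against as the whole source, since leaving these out of the totals shifted the log2 RPKM ratio (before the pseudocount) of every other gene by at most 0.49 (0.40 to 0.49 over the doses). The counting intervals lay wholly under a log2 ratio of -1 at all 3 doses for 100% of these genes. The genes were picked as 4-fold lower in the same counts, which nearly fixed this result in advance. It is therefore no separate evidence against sampling noise. In the simulated counts, counting error alone put 1 of 4541, 1 of 4521 and 2 of 4540 unchanged genes past 2-fold for the 3 comparisons. Whether the control library alone stands apart cannot be told apart from an effect of CuO, because there was 1 control and the median ratio of 50 over 1 mg/L was -0.17 (quartiles -0.54 and 0.21). An effect of CuO present at 1 mg/L may underlie these genes and stays untested.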
